A study of Mus musculus with 12 samples.

How the data were processed

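RNA of mouse bone-marrow-derived macrophages was measured on 12 Affymetrix arrays, in 6 groups of 2 replicates. Per the labels, the marrow cells were grown for 14 days with 10 ng/ml of the growth factor M-CSF, HEK293 cells were irradiated with UV (120 mJ/cm, as the labels give it) after 3 h of transfection with DNA where they received it, and were given to the macrophages 24 h later for 6 h. Per the labels, 300 ng of total RNA per sample was converted to biotin-labelled cDNA.

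The deposited table holds log2 values for 41345 probe sets. Per the submitters' processing notes they were made with RMA, a method that subtracts background, normalizes arrays to a common distribution and summarises probes; the version is not stated, nor whether all 12 arrays were normalized together. That the scale is log2 follows from the deposited values, whose medians run from 4.86 to 5.01 per array. The arrays' interquartile ranges were 2.02 to 2.29 in WT and 2.81 to 2.89 in SKO, and 10.5% to 11.1% of the values on WT arrays and 6.91% to 7.77% of those on SKO arrays occurred more than once on the same array. These differences follow the genotype, so a difference in handling or normalization between the genotypes cannot be separated from it. For arrays, only their number can be given as a limit on precision.

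The platform annotation gave a gene for 25335 probe sets, 1 symbol for 23521 and several for 1814, and 16010 probe sets were not listed in it. Symbols were updated by Entrez number through the RefSeq annotation of GRCm38.p6, which matched 23328 probe sets. The files name no genome build, so no positions are given. Of probe sets with 1 symbol, the one with the highest mean per gene was kept (1082 genes had more than 1), which left 22180 genes, and 15726 of these lay above the array's median on at least 2 arrays and were tested.

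One limma model (version 3.58.1, in R 4.3.3) with a mean per group was fitted to all 12 arrays, with moderated statistics (6 residual and 2.96 prior degrees of freedom), and 7 comparisons were taken from it: the effect of DNA and of feeding in each genotype, the difference of each between the genotypes, and the genotypes at rest. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes were called changed. The 34 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 33 lists with at least 3 tested genes, and again with an estimated correlation. Every adjusted p in the text is from limma. The model, filters, gene lists and most other settings were fixed before the data were examined.

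The text names Sting1; the 12 highest and 12 lowest changes past the threshold whose replicates do not overlap, or fewer; up to 4 genes of each list by p; and the genes Ifnb1, Cxcl10, Ccl5, Ifit1, Ifit3, Isg15, Irf7, Tnf, Il6, Il1b, Cd14, Abca1 and Hmox1. Ifit3 (0.08 with DNA in WT), Abca1 (0.06), Il1b and Cd14 were among those that passed in no DNA comparison, and Ifnb1 lay below the filter. Predicted genes, small RNA genes and olfactory or vomeronasal receptor genes were counted but not named by this rule; Snord13 is the exception and was picked after its values were seen. Interferon lists, where counted together, are the interferon-stimulated genes, the guanylate-binding proteins and immunity-related GTPases, the interferon-inducible chemokines and the MHC class I genes.

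The other settings chosen in advance were no filter and a stricter one (65th percentile), a trend with robust moderation, array weights, a block for the replicate number, quantile normalization, median centring, the mean of a gene's probe sets, all probe sets, a minimum of 2-fold, only the groups compared, and each array left out in turn. Fits of the 6 arrays of a genotype (3 residual degrees of freedom) and a weight per genotype were added after the spread of the WT arrays had been seen. Where an array was left out, the lone array of its group was assumed to vary like the other groups.

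The procedure was tested on simulated data with each genotype's own spread, with 200 of 15726 genes changed. For the effect of DNA in WT, the 12-array fit recovered 43% of 2-fold and 95% of 4-fold changes with 128 false calls, and the fit of the genotype's 6 arrays 0% and 77% with 3 false calls. For the effect of DNA in SKO, the 12-array fit recovered 50% and 93% with 0 false calls, and the 6-array fit 99% and 100% with 3. For feeding in WT the 12-array fit gave 160 false calls, and for feeding in SKO 0. In simulated WT data, a set of 50 genes shifted by 1 for the effect of DNA had a camera p of 2.44e-35, and 3 of 200 random sets were under 0.05. The genes were simulated as independent, so this does not test the preset correlation on lists whose genes vary together.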

Results

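Gene expression was measured on 12 mouse arrays, in 6 groups of 2. The question was what macrophages do when given dying cells that carry foreign DNA, and how far this needs STING. STING is an adaptor protein of the endoplasmic reticulum. The cyclic dinucleotide made by the DNA sensor cGAS switches it on, and it turns on type I interferon genes. Macrophages grown from the bone marrow of wild-type (WT) or STING-knockout (SKO) mice were kept alone (WT-Mock, SKO-Mock), fed UV-irradiated HEK293 cells for 6 h (WT-UV, SKO-UV), or fed such cells that had first been transfected with double-stranded DNA (WT-AT90ES-UV, SKO-AT90ES-UV). HEK293 is a human embryonic kidney cell line, and AT90ES is the labels' name for the DNA. Each change below is a difference of log2 values between means of 2 arrays per group, with its standard error (SE) from limma, and p-values are Benjamini-Hochberg adjusted over the 15726 genes tested. They measure the spread between these samples, which can be technical, because the labels do not say whether the replicates are separate cultures or animals. The number of arrays limits the precision. The spread between replicates differed by genotype. The SD between replicate arrays was 0.39 log2 in WT-Mock, 0.43 in WT-UV and 0.43 in WT-AT90ES-UV, against 0.14 in SKO-Mock, 0.17 in SKO-UV and 0.15 in SKO-AT90ES-UV. The shared spread is therefore on average too small for the WT comparisons and too large for the SKO ones. The array set and the genotype cannot be told apart here. Counts from the 6 arrays of a genotype alone therefore stand beside the counts from all 12.

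The STING gene, Sting1, was at a mean log2 level of 8.58 ± 0.03 (SD, n = 2) in WT-Mock, 8.10 ± 0.08 in WT-UV and 8.31 ± 0.05 in WT-AT90ES-UV. In SKO-Mock it was at 5.25 ± 0.94, in SKO-UV at 5.05 ± 0.57 and in SKO-AT90ES-UV at 5.07 ± 0.24. In macrophages alone, Sting1 fell by 3.33 ± 0.40 (SE) in SKO against WT, with limma's adjusted p = 0.0236. Whether its probe set lies in the deleted part of the gene is not known from the files. The call was lost without WT-Mock replicate 2 (adjusted p = 0.0629) and without SKO-Mock replicate 1 (-2.67, adjusted p = 0.27). At an unchanged -3.33 it was also lost with array weights (adjusted p = 0.0858), a block for the replicate number (0.0501), only the groups compared (0.208) and a weight per genotype (0.143), and at -3.39 after quantile normalization (0.069). In each of the 3 conditions both SKO arrays lay below both WT arrays.

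Interferon-stimulated genes rose with added DNA in WT macrophages. Comparing WT-AT90ES-UV with WT-UV asks what DNA in the cells given adds. The labels give no transfection step for the cells of the UV groups. What is called the effect of DNA, in both genotypes, therefore cannot be told apart from that of the transfection itself. Of 57 measured interferon-stimulated genes, 52 rose (54 adjusted over the list alone, 35 in the fit of the 6 WT arrays), with a median change of 2.23 and a camera adjusted p = 4.02e-68. Among them were Ifih1, a sensor of viral RNA (2.92 ± 0.13), Stat2, part of the transcription factor that interferon activates (2.78 ± 0.14), Herc6, which attaches ISG15 to proteins (2.96 ± 0.16), and Cmpk2, a mitochondrial nucleotide kinase (3.96 ± 0.23). Isg15 itself rose by 3.05 ± 0.21, Ifit1, which binds foreign RNA, by 3.54 ± 0.26, and Irf7, which amplifies interferon production, by 3.64 ± 0.29. The list's mean log2 level was 9.72 and 9.74 on the WT-AT90ES-UV arrays, against 7.12 and 7.44 on the WT-UV arrays and 6.74 and 6.86 on the WT-Mock arrays.

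**Figure D1:**
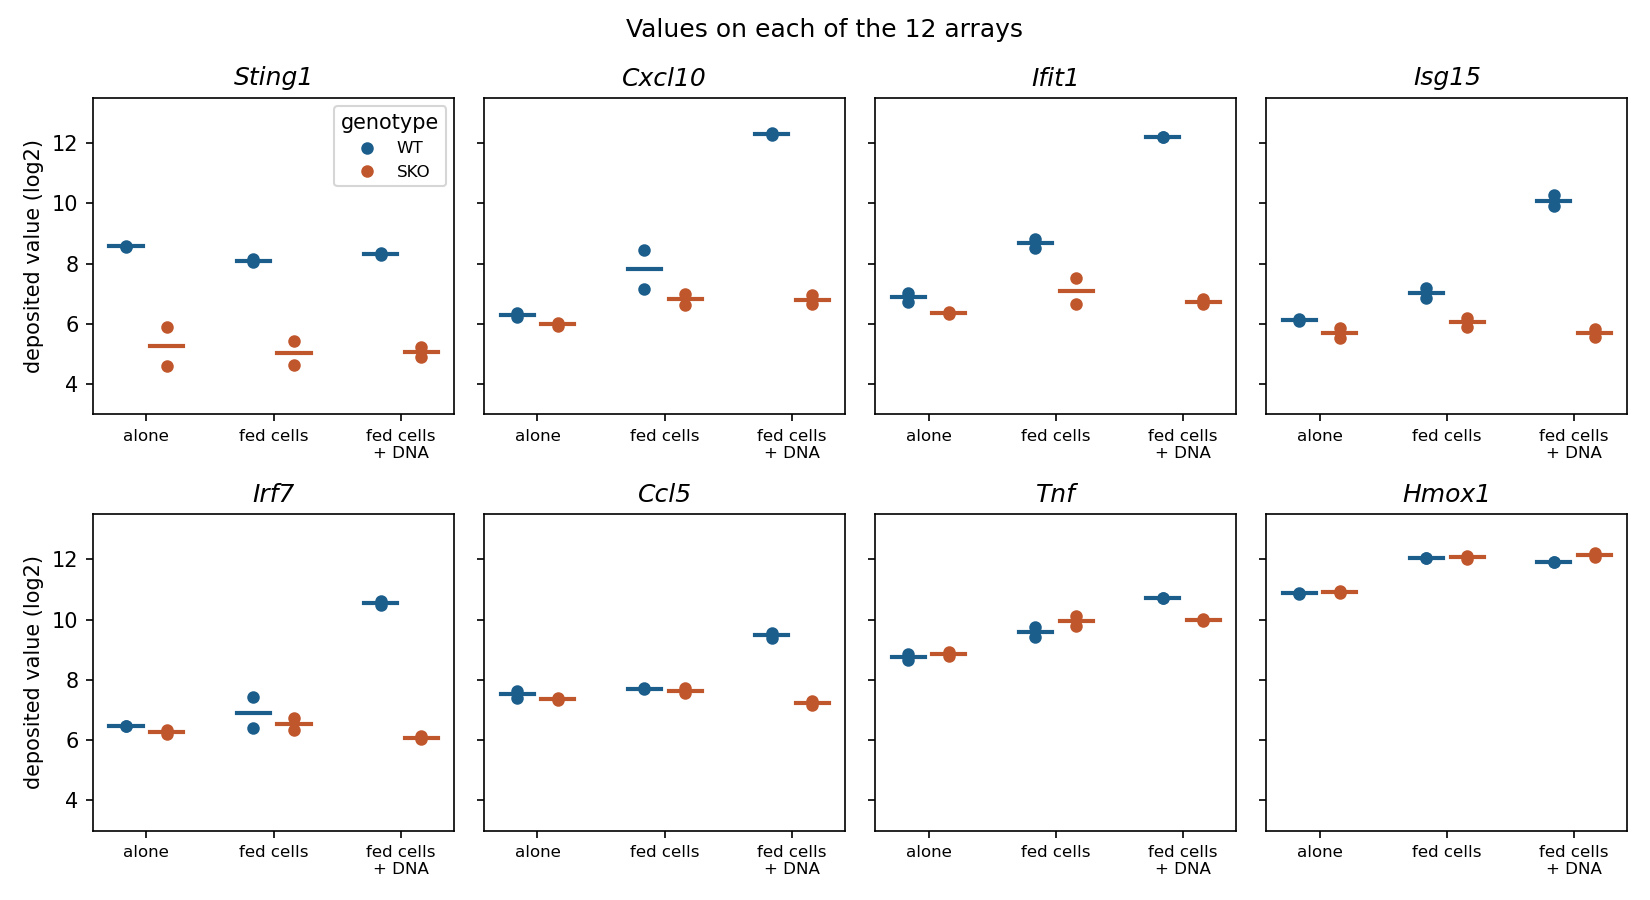
Deposited log2 value of 8 genes on each of the 12 arrays (points) with group means (lines), for macrophages alone, fed cells and fed DNA-loaded cells, WT in blue and SKO in orange. Cxcl10, Ifit1, Isg15, Irf7 and Ccl5 are highest on the WT arrays with added DNA, and Hmox1 is higher on all fed arrays than on those of macrophages alone.

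Other interferon-driven defence genes moved with them. Of 10 guanylate-binding proteins and immunity-related GTPases, which attack membranes around intracellular microbes, 9 rose (9 adjusted over the list alone, 7 in the WT-only fit; median 3.57, camera adjusted p = 7.68e-18). Among them were Gbp5 (4.33 ± 0.17), Iigp1 (4.70 ± 0.21), Irgm2 (3.51 ± 0.16) and Igtp (3.65 ± 0.22). Of 8 interferon-inducible chemokines, which draw monocytes and T cells, 6 rose (7 adjusted over the list alone, 4 in the WT-only fit; median 1.89, camera adjusted p = 4.02e-11). They included Cxcl10 (4.49 ± 0.35), Ccl12 (4.41 ± 0.27), Cxcl9 (3.00 ± 0.23) and Ccl5 (1.77 ± 0.15). Genes that speak to T cells rose as well. Of 18 costimulation genes, 8 rose (9 adjusted over the list alone, 4 in the WT-only fit; camera adjusted p = 3.89e-09). Among them were Cd69 (4.56 ± 0.20), the death ligand Tnfsf10 (4.01 ± 0.28), the cytokine Il15 (2.84 ± 0.27) and the checkpoint ligand Cd274 (2.09 ± 0.19). Of 16 MHC class I genes, 6 rose (8 adjusted over the list alone, 1 in the WT-only fit; camera adjusted p = 3.32e-08). The peptide transporter gene Tap1 was at 2.87 ± 0.29.

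The machinery of DNA sensing moved too. Of 16 genes in that list, 5 rose and 1, the RNA-sensing adaptor Mavs, fell (7 and 2 adjusted over the list alone, 1 and 0 in the WT-only fit; camera adjusted p = 0.00117). Cgas was at 1.59 ± 0.15, the inflammasome sensor Aim2 at 2.22 ± 0.24, Ifi204 at 3.16 ± 0.36 and Samhd1, which breaks down nucleotides, at 1.26 ± 0.13. Of 35 inflammatory genes driven by NF-kappa-B, 6 rose (7 adjusted over the list alone, 0 in the WT-only fit; median 0.28, camera adjusted p = 0.00119, adjusted p = 0.331 with an estimated correlation). They included Acod1, which makes itaconate (1.71 ± 0.19), Il6 (1.76 ± 0.28) and Tnf (1.12 ± 0.17). The other 6 lists called here kept their calls with an estimated correlation, with adjusted p from 0.00284 to 0.0404. The inflammatory cytokine Il1b (-0.20) and the endotoxin co-receptor Cd14 (-0.04) did not pass. Ifnb1, which codes for interferon beta, was too dim to pass the filter, at a mean level of 3.72 in WT-UV and 4.07 in WT-AT90ES-UV.

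In total 872 genes changed with added DNA in WT macrophages, 485 higher and 387 lower. The lower count was 606 without WT-AT90ES-UV replicate 1, 687 without WT-AT90ES-UV replicate 2, 648 (with 563 higher) with a trend and robust moderation, and 13 (with 139 higher) with array weights. In the fit of the 6 WT arrays alone 79 genes passed, 77 higher and 2 lower, and with only the 4 arrays of the comparison 0 did. Of the 77, 47 belong to the interferon lists. The 12 genes with the highest changes past the threshold ran from Tnfsf10 to Ifi209, an interferon-inducible gene (5.31 ± 0.45), and 11 of the 12 also passed in the WT-only fit. The lowest were Polr2l, a small RNA polymerase subunit (-2.74), and Cdk2ap1 (-2.22). Of the 12 lowest, Aadacl3 alone passed in the WT-only fit (-1.87, adjusted p = 0.0499), so the fall of single genes rests on the spread taken from all 12 arrays.

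In SKO macrophages none of these genes was called. Against SKO-UV, the change in SKO-AT90ES-UV was 0.50 for Cd274, 0.26 for Acod1, -0.02 for Cxcl10, -0.35 for Ifit1, -0.36 for Isg15, -0.45 for Irf7, -0.41 for Ccl5 and 0.03 for Tnf, each with an adjusted p of 1. Across the 57 interferon-stimulated genes the mean change was -0.09, with a 95% interval of -0.32 to 0.14, against 2.45 (1.99 to 2.91) in WT. Of the 15726 genes tested, limma called 0 changed, with 56 at an unadjusted p under 0.05. The fit of the 6 SKO arrays, which had the smaller spread, also called 0, with 1020 at an unadjusted p under 0.05. Small shifts of the whole list of interferon-stimulated genes (median -0.10, camera adjusted p = 0.00168, adjusted p = 0.585 with an estimated correlation) and of MHC class I genes (median -0.13, camera adjusted p = 0.0183, adjusted p = 0.585 with an estimated correlation) were downward. The first was not called without SKO-UV replicate 1 (adjusted p = 0.816), and the second not without SKO-UV replicate 1 (0.0616), SKO-UV replicate 2 (0.149) or SKO-AT90ES-UV replicate 2 (0.287).

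**Figure D2:**
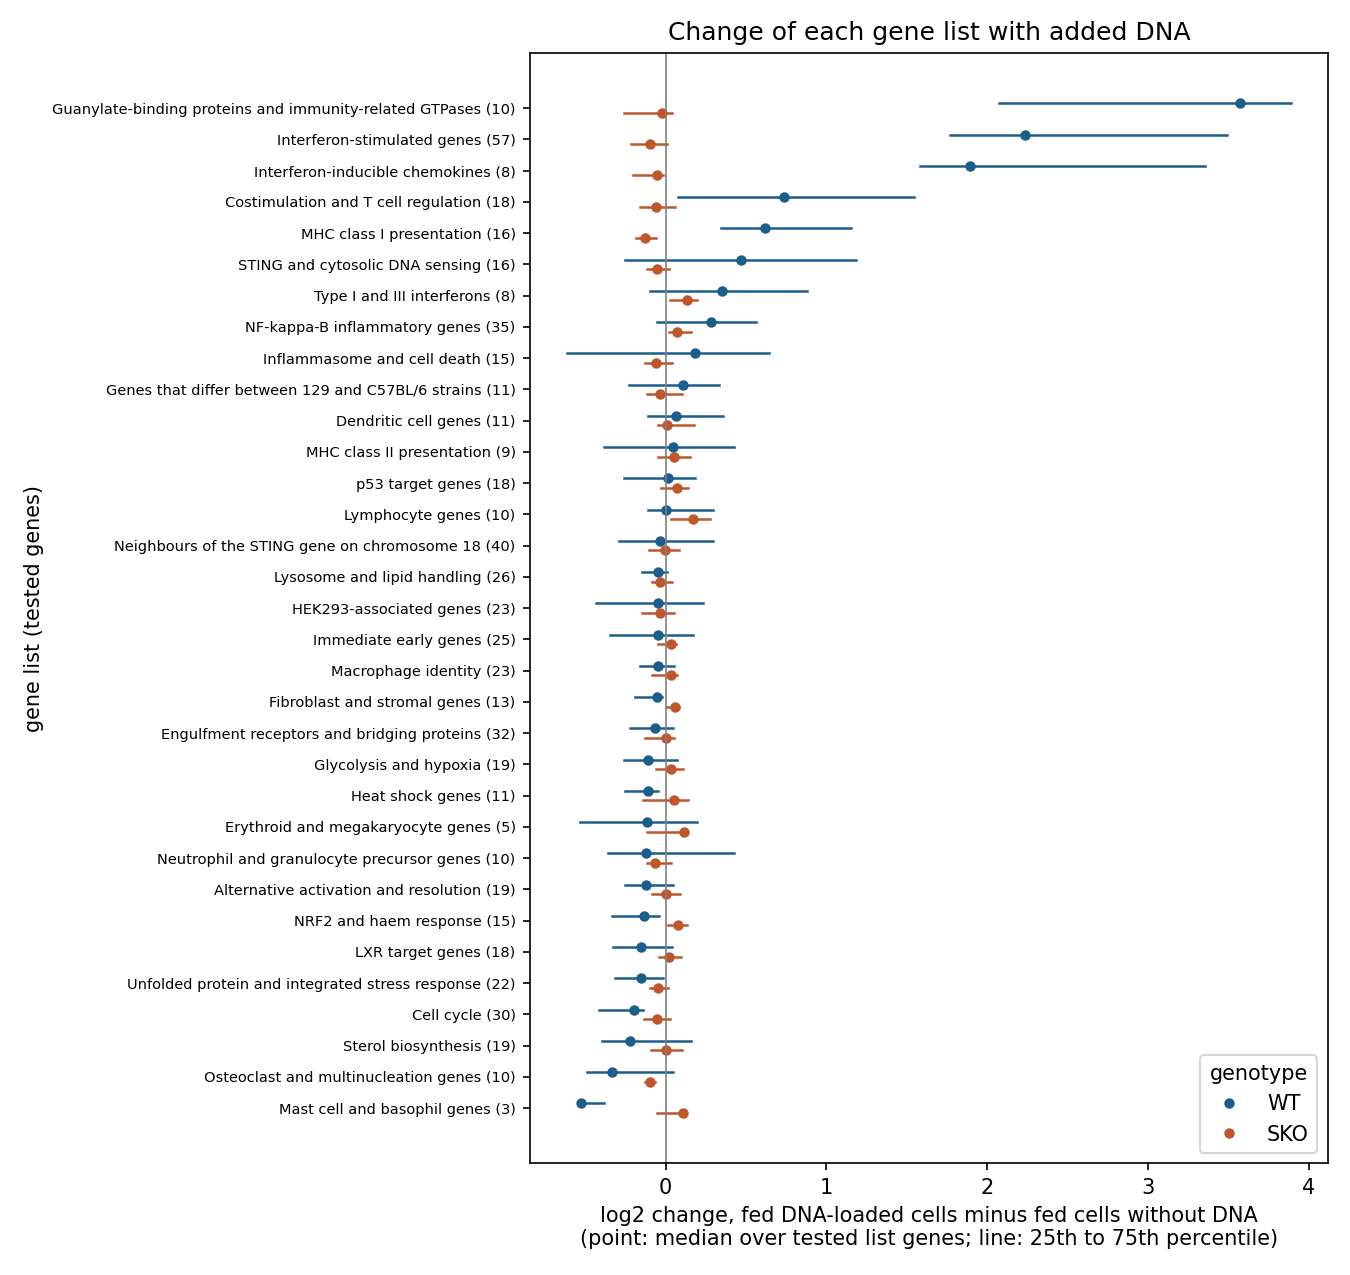
Log2 change with added DNA for the 33 gene lists with at least 3 tested genes, as the median over the list's tested genes (points) and the range from the 25th to the 75th percentile (lines), in WT (blue) and SKO (orange). The interferon-driven lists lie far above 0 in WT, at a median of 2.23 for interferon-stimulated genes, and near 0 in SKO, at -0.10.

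The effect of DNA differed between the genotypes, by a test of the difference itself. Ifit1 rose with DNA by 3.89 ± 0.37 more in WT than in SKO, Isg15 by 3.41 ± 0.30, Irf7 by 4.09 ± 0.42, Cxcl10 by 4.51 ± 0.50, Gbp5 by 4.76 ± 0.24 and Ccl5 by 2.18 ± 0.21. Tnf and Il6, which were called with DNA in WT, were not called as different between the genotypes. Their mean levels in SKO-UV and SKO-AT90ES-UV were 9.956 and 9.985 for Tnf and 3.678 and 3.736 for Il6. The missing call is therefore no sign that SKO shared the rise. Of 57 interferon-stimulated genes, 44 differed upward (55 adjusted over the list alone; camera adjusted p = 1.83e-83). So did 8 of 10 guanylate-binding proteins and immunity-related GTPases (8 adjusted over the list alone), 5 of 8 interferon-inducible chemokines (7), 6 of 18 costimulation genes (8), 4 of 16 MHC class I genes (6) and 4 of 16 DNA-sensing genes (5). In total 199 genes differed, 175 with a higher change in WT and 24 with a lower one. The lower count was 35 without WT-UV replicate 1, 75 without WT-UV replicate 2, 81 without WT-AT90ES-UV replicate 1, 90 without WT-AT90ES-UV replicate 2. It was 4 without SKO-UV replicate 1, 4 without SKO-UV replicate 2, 3 without SKO-AT90ES-UV replicate 1 and 4 without SKO-AT90ES-UV replicate 2, 11 with a block for the replicate number and 4 with array weights. All 77 genes that rose in the WT-only fit were among the 175, although both tests use the same WT arrays, and 26 of the 77 had a change above 0 with DNA in SKO. The count fell to 108 with array weights and to 103 with only the 8 arrays of the comparison. It was 75 without SKO-UV replicate 1, 77 without SKO-UV replicate 2, 72 without SKO-AT90ES-UV replicate 1 and 81 without SKO-AT90ES-UV replicate 2, against 328 without WT-UV replicate 2.

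Gene expression changed in both genotypes when irradiated cells without added DNA were given. Comparing the UV groups with the Mock groups asks what the irradiated cells themselves do. Serpinb2, an inhibitor of plasminogen activators, rose by 4.67 ± 0.34 in WT and 4.25 ± 0.34 in SKO, Angptl4, an inhibitor of lipoprotein lipase, by 3.32 and 2.76, and Fabp4, a fatty acid carrier, by 2.14 and 2.04. Dusp5, a phosphatase that acts on ERK, rose by 2.76 and 2.20, and Hmox1, which degrades haem, by 1.17 and 1.16. The Wnt agonist Rspo2 fell, with a change of -2.77 ± 0.23 in WT and -2.15 ± 0.23 in SKO, as did Hpgd, which inactivates prostaglandins (-2.13 and -1.94). Tnf rose by 0.85 ± 0.17 in WT and by 1.10 ± 0.17 in SKO; in WT its adjusted p was 0.0796 without WT-Mock replicate 1 and 0.0685 without WT-UV replicate 1. In SKO the adjusted p of Tnf was 0.305 without SKO-Mock replicate 1, 0.222 without SKO-Mock replicate 2, 0.122 without SKO-UV replicate 1 and 0.227 without SKO-UV replicate 2.

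Sterol synthesis was the group with the clearest fall. Of its 19 measured genes, 14 fell in WT (16 adjusted over the list alone; median -1.23, camera adjusted p = 3.7e-15) and 8 in SKO (15 adjusted over the list alone, 16 in the fit of the 6 SKO arrays; median -1.11, camera adjusted p = 1.49e-24). No member had a change above 0 in either genotype. Insig1, which restrains sterol synthesis and is itself switched on when sterols are low, fell in both (-2.01 ± 0.17 in WT and -1.58 ± 0.17 in SKO), as did Cyp51, a demethylase of the pathway (-1.86 and -1.40), and Srebf2, the pathway's transcription factor (-1.21 and -0.97). The cholesterol exporter Abcg1 rose by 2.11 ± 0.22 in WT and 1.73 ± 0.22 in SKO. The list of LXR targets, to which it belongs, did not move as a whole (median 0.09 in WT, camera adjusted p = 0.309; 0.03 in SKO, camera adjusted p = 0.77).

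Immediate early genes, which respond within minutes to growth and stress signals, rose in both genotypes. Of 25 measured, 7 rose in WT (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.14e-07) and 3 in SKO (6 adjusted over the list alone, 13 in the SKO-only fit; camera adjusted p = 1.23e-08). Dusp4 was at 1.73 ± 0.24 and 1.71 ± 0.24 and Ier3 at 0.98 ± 0.17 and 0.92 ± 0.17. The sterol and immediate early lists kept their calls with an estimated correlation in both genotypes. Of 15 genes of the NRF2 and haem response, which protects against oxidants, 5 rose in WT (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00223, adjusted p = 0.214 with an estimated correlation) and 3 in SKO (7 adjusted over the list alone and in the SKO-only fit; camera adjusted p = 1.14e-06, adjusted p = 0.0545 with an estimated correlation). The thioredoxin reductase gene Txnrd1 was at 0.84 ± 0.13 and 0.88 ± 0.13. Fibroblast and stromal genes lay lower, with 2 of 13 past the threshold in WT (5 adjusted over the list alone; camera adjusted p = 0.00223, adjusted p = 0.0994 with an estimated correlation) and 1 in SKO (3 adjusted over the list alone, 5 in the SKO-only fit; camera adjusted p = 7.92e-06, held with an estimated correlation). The chemokine Cxcl12 of that list fell in both (-1.16 and -0.96). The list was not dim: its median level was 9.63 in WT-Mock and 9.46 in SKO-Mock, against 9.45 and 9.36 for macrophage identity genes. Which cells of the cultures a change on feeding belongs to was not tested.

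Several lists were called on feeding in SKO and missed the threshold in WT. Alternative activation and resolution genes shifted upward (3 of 19 rose, 6 higher and 1 lower adjusted over the list alone, 7 and 2 in the SKO-only fit; camera adjusted p = 0.000128, adjusted p = 0.0545 with an estimated correlation). The growth factor gene Hbegf was at 1.82 ± 0.14 and the interleukin-1 antagonist Il1rn at 1.64 ± 0.20. Osteoclast and multinucleation genes shifted upward too (2 of 10 rose, 2 higher and 1 lower adjusted over the list alone and also in the SKO-only fit; camera adjusted p = 0.018, adjusted p = 0.0874 with an estimated correlation), with the integrin Itgb3 at 1.48 ± 0.15. Lists of p53 targets (median -0.29, 0 of 18 past the threshold, 3 adjusted over the list alone, 6 in the SKO-only fit; camera adjusted p = 0.000126, adjusted p = 0.0545 with an estimated correlation) and guanylate-binding proteins (median -0.24, 0 of 10, 0 adjusted over the list alone, 4 in the SKO-only fit; camera adjusted p = 0.0121, adjusted p = 0.0851 with an estimated correlation) shifted downward. The latter was not called without SKO-UV replicate 2 (adjusted p = 0.0553). In WT these lists had camera adjusted p = 0.0522 for alternative activation, 0.268 for osteoclast genes, 0.0665 for p53 targets and 0.0522 for guanylate-binding proteins. Their WT medians were 0.145, 0.199, -0.182 and 0.312 in that order, so only the guanylate-binding proteins lay in the opposite direction to SKO. Of these lists only the guanylate-binding proteins were called as different between the genotypes, and not with an estimated correlation (adjusted p = 0.0823).

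Other inflammatory and metabolic lists were also called in both genotypes, and in WT each of these calls was lost with an estimated correlation. Interferon-inducible chemokines shifted upward (4 of 8 rose in WT, 4 adjusted over the list alone; camera adjusted p = 0.0281, adjusted p = 0.214 with an estimated correlation; 1 in SKO, 3 adjusted over the list alone; camera adjusted p = 0.000128, adjusted p = 0.0415 with an estimated correlation). The monocyte attractant Ccl2 was at 2.51 ± 0.19 and 1.77 ± 0.19. Of 22 unfolded protein and stress response genes 2 rose in each genotype (7 higher and 1 lower in WT and 5 higher in SKO adjusted over the list alone; camera adjusted p = 0.0275 and 0.000126, adjusted p = 0.214 and 0.0467 with an estimated correlation), with Creld2, a protein of the endoplasmic reticulum, at 0.86 and 0.87. NF-kappa-B genes (5 of 35 rose and 1 fell in WT, 6 and 1 adjusted over the list alone; 2 rose in SKO, 4 adjusted over the list alone) had camera adjusted p = 0.0237 and 0.00213, adjusted p = 0.33 and 0.174 with an estimated correlation, with Ptgs2, the inducible cyclooxygenase, at 1.97 ± 0.13 and 1.52 ± 0.13. Costimulation genes (5 of 18 rose in WT, 6 higher and 1 lower adjusted over the list alone; 2 in SKO, 3 and 1 adjusted over the list alone) had camera adjusted p = 0.0137 and 0.0338, adjusted p = 0.141 and 0.1 with an estimated correlation, with Cd274 at 1.63 and 1.76. Lysosome and lipid handling genes (3 of 26 in WT and 2 in SKO, the same numbers adjusted over the list alone) had camera adjusted p = 0.0347 and 0.00188, adjusted p = 0.23 and 0.0874 with an estimated correlation, with the lipid droplet protein Plin2 at 1.35 ± 0.13 and 1.29 ± 0.13. Glycolysis and hypoxia genes (1 of 19 in WT, 0 in SKO, the same numbers adjusted over the list alone) had camera adjusted p = 0.0347 and 0.00117, adjusted p = 0.23 and 0.0851 with an estimated correlation. MHC class II genes lay lower (median -0.67 and -0.41; 2 of 9 past the threshold in WT, 4 adjusted over the list alone; 0 in SKO, 0 adjusted over the list alone), with camera adjusted p = 0.0137 and 0.00919, adjusted p = 0.33 and 0.29 with an estimated correlation. In the SKO-only fit 4 chemokines, 6 unfolded protein response, 9 NF-kappa-B, 4 lysosome and 5 glycolysis genes were higher, 5 costimulation genes were higher and 2 lower, and 2 MHC class II genes were lower. In the WT-only fit 0 genes of any list passed on feeding.

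Leaving out single arrays ended several of these list calls. In WT, omitting WT-Mock replicate 1 gave a camera adjusted p of 0.068 for NF-kappa-B genes, 0.121 for MHC class II, lysosome and glycolysis genes, and 0.088 for unfolded protein response genes. Omitting WT-Mock replicate 2 gave 0.0796 for chemokines and 0.0581 for glycolysis genes. Omitting WT-UV replicate 1 gave 0.232 for NF-kappa-B, 0.111 for lysosome, 0.0605 for unfolded protein response, 0.0526 for glycolysis and 0.133 for costimulation genes, and omitting WT-UV replicate 2 gave 0.193 for MHC class II, 0.0682 for lysosome, 0.0741 for unfolded protein response and 0.166 for glycolysis genes. In SKO, MHC class II genes were at 0.0615 without SKO-Mock replicate 2 and 0.0826 without SKO-UV replicate 1, costimulation genes at 0.0797 without SKO-UV replicate 1, and NF-kappa-B genes at 0.0516 without SKO-UV replicate 2.

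In total 896 genes changed on feeding in WT, 436 higher and 460 lower, with 282 lower without WT-Mock replicate 1 and 284 without WT-Mock replicate 2. In SKO 155 changed, 97 higher and 58 lower. These counts depend on whose spread is used. In the fit of the 6 WT arrays limma called 0 genes on feeding, with 1690 at an unadjusted p under 0.05. In the fit of the 6 SKO arrays it called 1889, 964 higher and 925 lower, the 155 among them. In the fit of all arrays the SKO count was 0 without SKO-Mock replicate 1, 5 without SKO-Mock replicate 2 (Chst11, Dusp5, Hbegf, Serpinb2 and Snord13), 1 without SKO-UV replicate 1 (Snord13) and 4 without SKO-UV replicate 2 (Hbegf, Klhl24, Serpinb2 and Snord13). All 155 genes had the same direction in WT. Of the 97 higher ones 88 were also called higher in WT, and of the 58 lower ones 52 were also called lower. No gene was called in opposite directions. WT and SKO share no arrays in these comparisons, but the fit gives both the same spread per gene, which favours the same genes. Across the tested genes, which are not independent replicates, their changes correlated at r = 0.486.

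**Figure D3:**
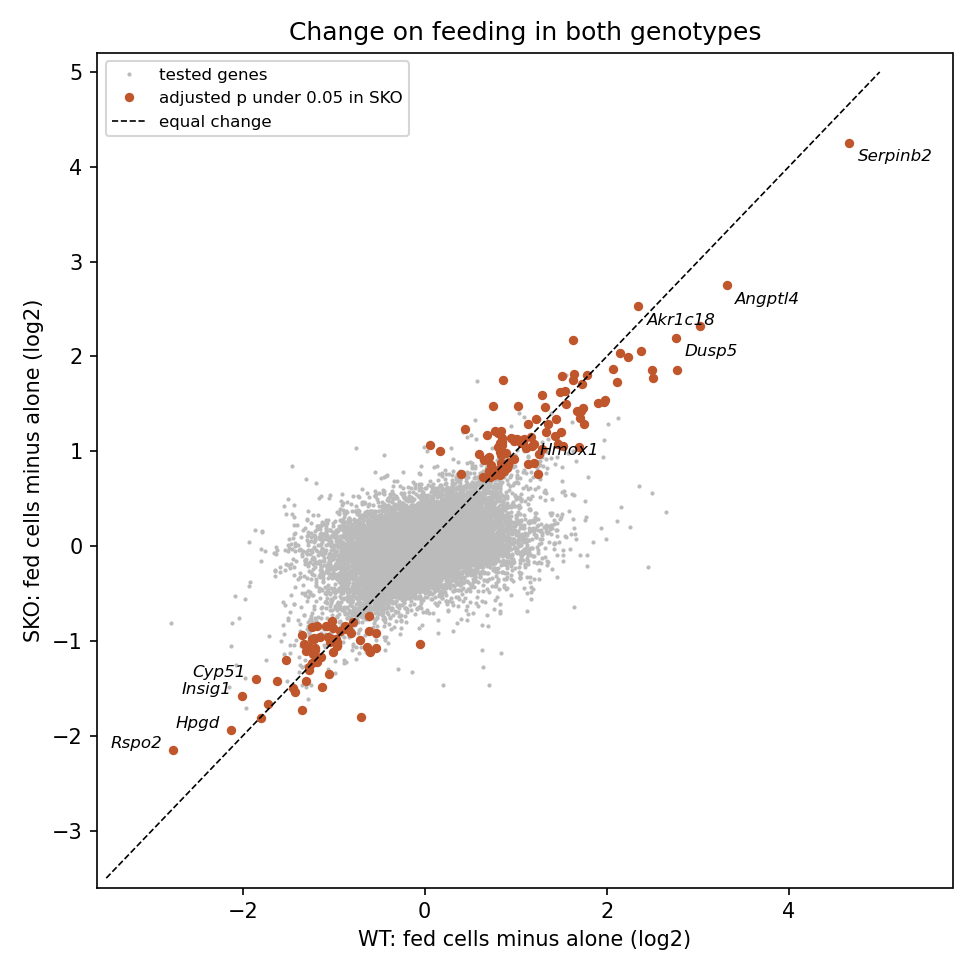
Log2 change on feeding irradiated cells in WT (x axis) against SKO (y axis) for the 15726 tested genes (grey), with the 155 genes past an adjusted p of 0.05 in SKO in orange and the line of equal change dashed. All 155 lie on the same side of 0 in both genotypes, with Serpinb2 at 4.67 and 4.25.

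Interferon genes on feeding were the one group whose shift differed between the genotypes as lists. In WT, 12 of 57 interferon-stimulated genes rose (18 adjusted over the list alone; median 0.32, camera adjusted p = 1.57e-06, adjusted p = 0.214 with an estimated correlation), with Cmpk2 at 2.36 ± 0.23, Ifi205 at 2.01 ± 0.25, Ifit1 at 1.80 ± 0.26 and Usp18, which takes ISG15 off proteins, at 1.77 ± 0.28. In SKO 0 of 57 passed (1 higher and 2 lower adjusted over the list alone, 3 and 4 in the SKO-only fit; camera adjusted p = 0.696). The difference had a median of 0.43 for interferon-stimulated genes (camera adjusted p = 1.53e-11, adjusted p = 0.303 with an estimated correlation) and 0.57 for guanylate-binding proteins and immunity-related GTPases (camera adjusted p = 3.03e-05, adjusted p = 0.0823 with an estimated correlation). Gene by gene limma called 0 differences in the feeding effect, with 1011 at an unadjusted p under 0.05, where chance alone gives 786.3. The difference was 1.72 ± 0.33 for Cmpk2 (adjusted p = 0.367), and Ifit1 had an adjusted p of 0.669 and Cxcl10 of 0.909. Without WT-UV replicate 1, 1 gene was called, Dgkq (-3.41 ± 0.25). It was picked after its values were seen.

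In macrophages kept alone, the number of genes called between the genotypes depended on the setting. Limma called 27 genes, 14 higher and 13 lower in SKO, among them Rpl34, a ribosomal protein gene (1.74 ± 0.20), and the claudin gene Cldn24 (-2.31 ± 0.22). Interferon-stimulated genes lay slightly lower in SKO (median -0.13, 0 of 57 past the threshold and 2 adjusted over the list alone, camera adjusted p = 2.17e-05, adjusted p = 0.613 with an estimated correlation). Over all tested genes the median difference was 0.15, against 0.04 after quantile normalization and 0.21 after centring, so the list lay lower still against the other genes. The count was 516 without a filter (77 higher and 439 lower) and 74 with all probe sets (21 higher and 53 lower). It was 0 with a block for the replicate number, where Sting1, Rpl34 and Cldn24 each had an adjusted p of 0.0501, and 0 with only the groups compared. It was 0 after quantile normalization and 34 (22 higher and 12 lower) after centring each array on its median, and 0 without SKO-Mock replicate 1, 1 (Sting1) without SKO-Mock replicate 2, 13 without WT-Mock replicate 2 and 66 without WT-Mock replicate 1. Without SKO-Mock replicate 1, Rpl34 and Cldn24 each had an adjusted p of 0.27, without SKO-Mock replicate 2 they had 0.342 and 0.288, and without WT-Mock replicate 2 Rpl34 had 0.0597.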

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

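The tests chosen only after the result was seen are those of noise in silent genes, of precision, uptake and signal scale on the SKO arrays, of a response shared with WT, of small nucleolar RNA, and the splits of the arrays with their simulation, and the simulation with the genes called on the WT arrays alone, whose use beside the bound set beforehand was also decided afterwards, as well as the fits of the 6 arrays of a genotype; the simulation with no change and the test of human RNA were set beforehand.

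The effect of added DNA differed between WT and SKO macrophages for 199 genes, by a test of the difference itself. The differences with the highest values were 5.71 for Ifi209, 5.12 for Ifit1bl1, 5.055 for Ccl12, 4.76 for Gbp5, 4.74 for Trim30c, 4.54 for Cd69, 4.53 for Iigp1, 4.51 for Cxcl10, 4.45 for Ifi213, 4.28 for Mx1, 4.24 for Ifit3b and 4.19 for Ddx60. Of these, Trim30c was not called without WT-AT90ES-UV replicate 2 (adjusted p = 0.0577), SKO-UV replicate 1 (0.142), SKO-UV replicate 2 (0.136), SKO-AT90ES-UV replicate 1 (0.159) or SKO-AT90ES-UV replicate 2 (0.106), and Mx1 not without SKO-UV replicate 1 (0.0622), SKO-AT90ES-UV replicate 1 (0.0755) or SKO-AT90ES-UV replicate 2 (0.061). The differences were 2.18 for Ccl5, 3.885 for Ifit1, 4.09 for Irf7 and 3.41 for Isg15. The lowest were -2.70 for Polr2l, -2.10 for Aadacl3, -1.94 for Cdk2ap1, -1.67 for Vash2, -1.59 for Napg, -1.58 for Lsm3, -1.56 for Epn3, -1.56 for Wee1, -1.55 for Slc2a5, -1.49 for Ankrd23, -1.45 for Osgin2 and -1.395 for Ube2v2. Of the 12 lowest, all but Aadacl3 and Wee1 lost their call when at least one of the 8 arrays was left out; without SKO-UV replicate 1, for example, the adjusted p was 0.171 for Polr2l and 0.0734 for Cdk2ap1.

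The lists whose DNA effect differed had median differences of 2.31 for interferon-stimulated genes, 3.68 for guanylate-binding proteins and immunity-related GTPases, 2.14 for interferon-inducible chemokines, 0.884 for costimulation, 0.676 for MHC class I, 0.473 for DNA sensing, 0.130 for NF-kappa-B genes and -0.244 for the NRF2 and haem response. The last 2 were not called with an estimated correlation (adjusted p = 0.493 each). NF-kappa-B genes were also not called without WT-UV replicate 2 (0.202), WT-AT90ES-UV replicate 2 (0.143) or SKO-UV replicate 2 (0.167), and NRF2 genes not without WT-UV replicate 1 (0.0612), WT-UV replicate 2 (0.109), WT-AT90ES-UV replicate 1 (0.248), SKO-UV replicate 1 (0.0895) or SKO-AT90ES-UV replicate 2 (0.0976). The effect of feeding differed for interferon-stimulated genes (median 0.425) and guanylate-binding proteins and immunity-related GTPases (0.567), and neither was called with an estimated correlation (adjusted p = 0.303 and 0.0823).

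The first pattern weighed is the 387 genes lower with added DNA in WT, of which 2 pass on the WT arrays alone. A shared spread that is too small for the WT arrays gave a mean of 14.14 lower calls in simulated data with no change, 3.65% of the 387, which met the bound set beforehand against this explanation, but 53.86 (13.92%), which did not, when the genes called on the WT arrays alone were changed as estimated. The simulated noise also falls short of the noise on these arrays. Split without regard to DNA, with the spread taken from the other 8, the same 4 WT arrays gave 785 and 666 lower calls. Split by DNA in that fit, they gave 1653. The simulation put through that fit gave a mean of 388 and at most 455 (479 and 556 with the spread as measured). These counts come from another fit than the 387, so how many of the 387 a spread that is too small may account for is not known, and such calls cannot be told apart from a fall. Noise in genes silent in macrophages is not excluded either, since receptor genes of smell and taste made up 1 of the 387, a ratio of 0.171 to their share among tested genes with a 95% interval of 0.024 to 1.22, and a true fall of some genes with DNA stays open.

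The second pattern is that 0 genes passed with added DNA in SKO, with 56 at an unadjusted p under 0.05 where chance gives 786.3, and with 1020 in the fit of the 6 SKO arrays. The tables argue against too little precision for the interferon-stimulated genes as a list. The upper 95% bound of their mean change was 0.135, below the bound of 0.613 taken from the WT change. For other genes only the simulation speaks to precision. There the 12-array fit recovered 50% of 2-fold changes with DNA in SKO, and the 6-array fit 99%. Sterol genes on feeding had a mean change of -0.97 in SKO (95% interval from the spread between arrays -1.11 to -0.83) and -1.16 in WT (-1.44 to -0.88). The ratio was 0.838, with 0.758 to 0.922 when genes were resampled. These values argue against a strongly compressed scale for the sterol genes only, a list called in both genotypes and chosen after results were seen. The interquartile ranges were 2.81 to 2.89 on SKO arrays and 2.02 to 2.29 on WT arrays. They argue against a compressed scale over the middle range of the SKO values. The highest value per array lay lower in SKO, at 13.20 to 13.70 against 13.93 to 13.95 in WT. For genes at high levels, and for single genes, a compressed scale stays open. The test first chosen for this, the slope of SKO on WT over genes called in WT, gave 0.480. It decided nothing and was replaced after it was seen. Poor uptake of the DNA-loaded cells stays open: the 896 genes that changed on feeding in WT moved in the WT direction in SKO by a mean of 0.497 with DNA-loaded cells (95% interval from the spread between arrays 0.459 to 0.535) and by 0.507 (0.469 to 0.545) with cells without DNA, but no table shows that this response needs engulfment. A need for STING, the difference the design names, also stays open. The array set is confounded with the genotype. Other changes in the knockout mice were tested only as a shared direction of the Sting1 neighbours and of the strain genes.

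The third pattern is the 964 genes higher after feeding on the SKO arrays alone. A response that WT cells share would make most of them higher in WT, and 87.24% were, on arrays that the SKO comparison does not use. Human RNA from the HEK293 cells read by mouse probes may add to it and is not excluded. The HEK293-associated list had a median change of 0.212 in SKO, where 0.25 had been set as the mark. The 95% interval of that median was -0.10 to 0.28 when genes were resampled, and it holds no spread between arrays. For small nucleolar RNA genes the median was 0.079, inside the -0.07 to 0.09 of random lists, which by the criterion written for this test counts against human snoRNA as their source; it is left open because 8 were higher and 0 lower on the SKO arrays alone. Shared response and carried-over human RNA therefore cannot be told apart for single genes, since WT macrophages were given the same kind of cells.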

How the results depend on the processing

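The fits of the 6 arrays of a genotype and the weight per genotype were chosen after the spread of the WT arrays had been seen; all other settings were set beforehand. No call of a named gene or list reversed its direction under the settings run, and the count for DNA in SKO was 0 under every setting.

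The counts changed with whose spread is used. With array weights the counts were 152 for DNA in WT, 108 for its difference between the genotypes, 37 for feeding in WT and 2170 for feeding in SKO, and Sting1 had an adjusted p of 0.0858 at -3.33. With a weight per genotype they were 177 for DNA in WT, 34 for feeding in WT, 2326 for feeding in SKO and 15 at rest, and Sting1 (-3.33) had an adjusted p of 0.143. On the 6 arrays of a genotype they were 79 for DNA in WT, 0 for feeding in WT and 1889 for feeding in SKO. With only the groups compared they were 0 for DNA in WT, 103 for its difference, 0 for feeding in WT, 1470 for feeding in SKO and 0 at rest, and Sting1 (-3.33) had an adjusted p of 0.208. These settings give the noisier WT arrays less weight or their own spread, or leave fewer arrays.

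Without a filter 74 genes passed for feeding in SKO and 516 at rest (77 higher and 439 lower), and with the stricter filter 308 for feeding in SKO. With a trend and robust moderation 1345 passed for feeding in WT, 557 for feeding in SKO and 11 at rest. With all probe sets tested 60 passed for feeding in SKO and 74 at rest (21 higher and 53 lower). With a minimum of 2-fold, 526 remained for DNA in WT and 445 for feeding in WT, by construction. After quantile normalization 0 passed at rest, and Sting1 was at -3.39 with an adjusted p of 0.069. The cause of the other changes was not tested.

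Little sign of pairing by replicate number was seen: of 15 pairs of groups, 1 had a correlation of deviations over 0.1 (range -0.104 to 0.108). The labels do not say what a number marks, so a shared animal or day is not excluded. With the number as a replicate block the counts were 719 for DNA in WT, 0 for DNA in SKO, 148 for the difference, 641 and 108 for feeding in WT and SKO, 0 for its difference and 0 at rest, and Sting1 (-3.33) had an adjusted p of 0.0501.

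Leaving out 1 array at a time gave 1002 to 1259 genes for DNA in WT, 0 to 0 in SKO, 72 to 328 for the difference, 626 to 1101 for feeding in WT, 0 to 5 in SKO, 0 to 1 for its difference and 0 to 66 at rest, and Sting1 from -4.00 to -2.67. Of the 47 calls of lists, 28 were lost with an estimated correlation, and 0 changed sign under quantile normalization or centring; the replicate block changed no list call. The number of arrays limits all of these, as 2 per group leave the spread to be borrowed across groups. A fit without 1 array takes the spread of the lone array left in that group from the other groups. Its counts therefore do not show how stable the calls are. For DNA in WT every such count lay above the 872 of the full fit, yet many of the 872 were not called again.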

Other observations

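All tests in this part were among those set beforehand, except those of Snord13, which was picked after its values were seen.

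Of the 33 gene lists tested, 15 were called in no comparison. Engulfment receptors and bridging proteins did not move as a group in any comparison (lowest camera adjusted p = 0.322), though single members rose on feeding in SKO, among them Itgb3 (1.48 ± 0.15) and the inhibitory receptor Cd300lf (1.24 ± 0.17, adjusted p = 0.0135). Macrophage identity genes had a lowest adjusted p of 0.238, and Cx3cr1, the fractalkine receptor, fell on feeding in both genotypes (-1.07 ± 0.15 and -0.96 ± 0.15). The lowest adjusted p was 0.115 for type I and III interferon genes (DNA in WT, median 0.348; 0.0255 without WT-UV replicate 1), 0.337 for inflammasome and cell death genes, 0.0699 for cell cycle genes (at rest, median 0.283), 0.0544 for heat shock genes and 0.309 for LXR targets. The lists called in no comparison also include blood cell markers, with a lowest adjusted p of 0.489 for neutrophil, 0.238 for dendritic cell, 0.0699 for lymphocyte, 0.603 for erythroid and megakaryocyte, and 0.0544 for mast cell and basophil genes. Neighbours of Sting1 on chromosome 18 had a lowest adjusted p of 0.125 and genes known to differ between laboratory mouse strains of 0.24, both for feeding in SKO. Because camera looks for a shared direction, these tests do not exclude neighbours or strain genes that differ in either direction. HEK293-associated genes had a lowest adjusted p of 0.112.

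The interferon beta gene Ifnb1 was dim throughout. Its mean level was 3.70 in WT-Mock, 3.72 in WT-UV and 4.07 in WT-AT90ES-UV, and 3.11, 3.05 and 3.11 in the matching SKO groups, so it was below the filter. In the fit without a filter its change with DNA was 0.35 ± 0.27 in WT (adjusted p = 0.51) and 0.06 ± 0.27 in SKO (adjusted p = 1), although both WT-AT90ES-UV arrays lay above both WT-UV arrays.

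The signal of Snord13, a small nucleolar RNA that guides acetylation of ribosomal RNA, rose on feeding by 3.02 ± 0.15 in WT (adjusted p = 0.000173) and by 2.32 ± 0.15 in SKO (adjusted p = 0.0017). In limma's fits of the 6 arrays of a genotype the adjusted p was 0.147 in WT and 0.000142 in SKO. Whether human Snord13 of the HEK293 cells was read by the mouse probes was not tested. Rpl34 was at a mean level of 5.31 ± 0.22 (SD, n = 2) in WT-Mock, against 7.96 in WT-UV, 6.37 in WT-AT90ES-UV and 7.05, 7.41 and 7.21 in the SKO groups.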
